A study of Homo sapiens with 4 samples.

How the data were processed

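The series measured RNA from Huh7 hepatocellular carcinoma cells after 4 days of mock medium or 300 µM H2O2, with 2 libraries per group. Per the labels, RNA was taken with a column kit, and complementary DNA libraries were made from total RNA with an Illumina TruSeq RNA kit. The groups came from the treatment label. The titles gave each group a library H and a library Q, and the meaning of the letters was not given in the sources used here. They name the libraries and were not a term of the main test. They also served for ratios within a letter, as a block in an alternative fit and to group the libraries.

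Per the submitters' processing notes, the tools were CASAVA, Bowtie 0.12.2, TopHat 1.3.3 and Cuffdiff, and the genome builds named were mm8, hg19 and GRCh37, with no roles given. The counting program, the annotation and the use of strand were not given in the sources used here. The deposited tables listed 58146 transcript models per library, of which 34587 were RefSeq mRNAs, 21536 long intergenic RNA models and 2023 other RNAs. They gave chromosome and strand for each model, and start and end positions were not used here.

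Per the file headers, the deposited tables held a read count and an FPKM value for each transcript model. The deposited counts were whole numbers, and isoforms of a gene repeated nearly the same count. Their totals were 193168287, 203313927, 208693684 and 212113377 in mock H, mock Q, H2O2 H and H2O2 Q, above the 78126878, 88409567, 83462944 and 86492977 mapped mates of the deposited alignment summaries. With 1 model per gene, that of the highest count, the totals were 103851326, 108117565, 113082498 and 112972746. A read was therefore counted in more than 1 isoform, and a summed count overstates the counting precision of genes with many isoforms. The totals with 1 model per gene still exceeded the mapped mates in every library, so repeated counting over isoforms does not account for the whole excess, and its other sources were not tested. The deposited FPKM values totalled 12470303 to 14342349 per library and did not follow read count over transcript length. The number of reads that would make an FPKM correct fell with exon number in every library. In mock H its median over transcripts with at least 1000 reads was 83860165 for 1 exon, 48728720 for 2, 14035102 for 5, 6823644 for 10 and 3625800 for 20. A sum of the exons' own values would behave in this way. FPKM was therefore used only for the expression filter, for the description of separated genes and for alternatives, and it raises genes with many exons in both. Exon numbers, lengths and GC content came from GENCODE v29 on GRCh38, matched by RefSeq accession, and neighbouring genes from a RefSeq table of GRCh38.p14. Coordinates of that build are not printed.

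The counts of all models with the same gene symbol were summed. Genes with FPKM of at least 1 in at least 2 of the 4 libraries were kept, which left 24235. Library sizes were scaled by TMM (factors 0.937, 1.10, 0.926 and 1.05 in the order above), and levels are TMM-normalised CPM, the count scaled to the effective library size. H2O2 was compared with mock by the two-sided quasi-likelihood test of edgeR 4.0.16 with treatment as the sole term, which left 2 residual degrees of freedom (prior degrees of freedom 3.11, common biological coefficient of variation 0.311). P-values were adjusted by Benjamini and Hochberg at 5%. The design fixed before the data were examined named limma on log2(FPKM + 1), or edgeR if the tables held whole counts, so edgeR was used and limma became an alternative. Within-letter ratios used CPM plus 0.1. A gene was called separated when both H2O2 values of FPKM plus 1 lay at least 2 times above, or below, both mock values. Where a group had 0 reads the fold was bounded with 3 reads over the group. With 1 to 3 reads the ratio is given with an exact 95% interval, which covers counting error only. The read numbers behind these bounds and intervals are those of the gene's highest-count model, while the other folds come from summed counts.

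In all, 37 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1, with the correlation between genes preset at 0.01 and adjustment over the 37 lists. Camera with an estimated correlation and fry were alternatives. Of the 13 lists past 5%, 0 passed with an estimated correlation and 0 with fry, which asks whether the genes of a list move 1 way on balance. Both alternatives had 2 residual degrees of freedom to work with, so a call lost under them does not show that a list was unchanged. The lists covered oxidative, stress and hypoxia responses, cell division and DNA repair, liver functions and metabolism, epithelial and mesenchymal genes, inflammation and growth signals, ribosomal and histone genes, and markers of stromal, endothelial and blood cells.

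The named genes followed a rule fixed in advance. It took the 10 genes of largest fold change in each direction past the threshold or, as here, where none passed, the 10 of largest fold among the separated genes. It added the 4 members of largest change in the direction of each list past 5%, 2 members of largest change in each other list, and 12 genes of peroxide response, liver identity and proliferation. Genes named outside this rule are marked as picked after their values were seen. Some genes that the rule takes are not reported here.

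The gene test was run on 5 simulated datasets with the fitted means, library sizes and dispersions of the H2O2 and mock libraries, with 24235 genes in the fit and 200 changed in each. edgeR recovered 3.58% of 335 genes changed 2-fold, 46.9% of 335 changed 4-fold and 81.8% of 330 changed 8-fold. DESeq2 1.42.0 recovered 19.1%, 72.8% and 87.9%. Of 120175 unchanged genes edgeR called 63 and DESeq2 313, which was more than 5% of all simulated calls for each. Of 5 simulated lists of 20 genes raised by 0.5 log2 units camera called 5 at an unadjusted p under 0.05, and of 5 unchanged lists 0. The genes were simulated independently of each other, so this cannot show whether the preset correlation is too small for real lists. All analyses were run in R 4.3.3.

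The alternatives were no expression filter, a mean FPKM of at least 5, the filterByExpr function, median log ratio size factors, quantile normalisation, limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1, with and without an intensity trend or robust fit, each model tested on its own, DESeq2, the letter as a block, a 1.5-fold separation, and each library left out in turn. Alternatives added after the data were seen were the highest-count model of each gene, genes with an mRNA alone and separation on CPM. Limma with a pseudocount of 1, the test named in advance for FPKM values, was listed as an alternative at the same time. Separated counts for the other 2 ways of dividing 4 libraries into pairs were computed as well.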

Results

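RNA was sequenced from Huh7 cells, an established human hepatocellular carcinoma line. The cells had been given medium with 300 µM hydrogen peroxide (H2O2) or mock medium for 4 days, with the medium replaced daily. There were 2 libraries in each group, and the titles gave 1 library of each group the letter H and the other the letter Q. The meaning of the letters was not given in the sources used here. The libraries held between 78126878 and 88409567 mapped read mates. The mapped share was 90.5% and 87.4% in mock libraries H and Q, and 91.7% and 90.9% in H2O2 libraries H and Q. Reads were tabulated for 58146 transcript models under 42067 gene names, of which 24235 passed the expression filter. These were 15381 genes with a RefSeq mRNA, 8121 long intergenic RNA models and 733 others. Levels are TMM-normalised CPM, counts scaled to the effective library size, given as mean ± SD with n = 2, and all fold changes are log2 of H2O2 over mock.

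The comparison asked how the Huh7 transcriptome differed after 4 days of H2O2. Genes of epithelial cell junctions and identity were lower in the H2O2 libraries. CDH1 on chromosome 16, which encodes E-cadherin, measured 138 ± 33 CPM in mock and 48.0 ± 5.20 CPM in H2O2 (log2 fold change −1.52, SE 0.25). ESRP1 on chromosome 8, a splicing factor of epithelial cells, measured 22.5 ± 3.51 and 4.62 ± 0.711 CPM (−2.29, SE 0.25). Genes of DNA replication and mitosis were higher by a median of 0.49 and 0.46 log2 units. These group differences passed with a preset correlation between genes and lost their call with an estimated one (adjusted p = 0.889 for epithelial genes and 0.894 for both cell division lists) and with fry, and no single gene passed the test over all genes.

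The epithelial list fell as a group, with 14 of its 15 measured members lower and a median of −0.49 (camera, adjusted p = 4.2e-08). With an estimated correlation between genes the adjusted p was 0.889. The median was −0.65 between the libraries of letter H and −0.45 between those of letter Q. After ESRP1 and CDH1 the largest differences were in ST14, a membrane serine protease (−1.27, SE 0.76), and in CLDN4, a tight junction claudin (−1.23, SE 0.34). Over all genes no member passed (edgeR, adjusted p = 0.53 for ESRP1 and 0.729 for CDH1), and 2 members, ESRP1 and CDH1, passed when adjusted over the list alone (lowest adjusted p = 0.00336). The list stayed past 5% without each library in turn.

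**Figure D1:**
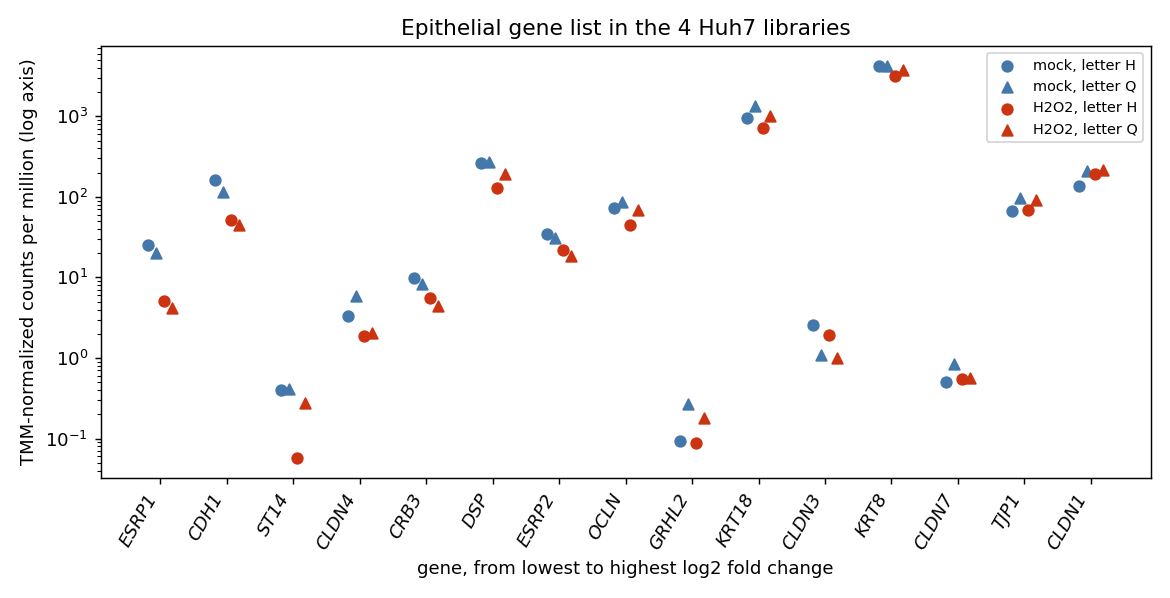
TMM-normalised CPM (log axis) of the 15 epithelial list genes in each of the 4 libraries, with mock in blue, H2O2 in red, circles for letter H and triangles for letter Q. CDH1 lay at 161 and 115 CPM in the mock libraries and at 51.7 and 44.4 CPM in the H2O2 libraries, and ESRP1 at 25 and 20.03 against 5.12 and 4.12 CPM.

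The fetal liver and hepatic progenitor list also passed in the downward direction, with 7 of 12 measured members lower and a median of −0.23 (adjusted p = 0.0288, and 0.894 with an estimated correlation). EPCAM, an epithelial adhesion molecule, measured 120.3 ± 36.7 CPM in mock and 34.9 ± 0.662 CPM in H2O2 (−1.79, SE 0.27). The stem cell transcription factor SALL4 was lower by a log2 difference of −0.97 (SE 0.22). EPCAM and SALL4 were the 2 members to pass when adjusted over the list alone (lowest adjusted p = 0.0129), and 0 passed over all genes. The adhesion receptor CD44 (−2.34, SE 0.96) and PROM1 (−1.02, SE 0.55) varied more between libraries. The fetal serum protein AFP and the proteoglycan GPC3, also of this list, differed by 0.42 (SE 0.72) and 0.32 (SE 0.50). The list lost its call without mock library H (adjusted p = 0.0941), H2O2 library H (0.0618) or H2O2 library Q (0.103), and under 13 of 20 alternative settings in all.

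Cell division genes rose as groups. All 22 DNA replication and G1/S genes were higher in H2O2, with a median of 0.49 (camera, adjusted p = 3.44e-08), and all 20 mitotic genes were higher, with a median of 0.46 (adjusted p = 4.2e-08). Both had an adjusted p of 0.894 with an estimated correlation, and both stayed past 5% without each library in turn. The replicative helicase subunit MCM6 measured 38.3 ± 3.01 and 63.8 ± 7.85 CPM (0.73, SE 0.20), and the helicase subunit MCM4 (0.69, SE 0.23) and the ribonucleotide reductase subunit RRM2 (0.69, SE 0.26) differed by about the same. Among mitotic genes the kinase CDK1 measured 118 ± 17.9 and 199 ± 66.3 CPM (0.75, SE 0.30), followed by TOP2A (0.68, SE 0.37), TTK (0.64, SE 0.21) and AURKA (0.64, SE 0.28). The proliferation marker MKI67 lay at 178 and 134 CPM in mock libraries H and Q and at 266 and 179 CPM in H2O2 libraries H and Q (0.51, SE 0.28, adjusted p = 0.749). Within letter H the medians of the 2 lists were 0.59 and 0.48, and within letter Q 0.38 and 0.51. In both groups the median mitotic gene was lower in library Q than in library H, by −0.51 in mock and −0.35 in H2O2.

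Heat shock proteins rose as a group, with 13 of 13 higher and a median of 0.51 (camera, adjusted p = 2.05e-05, and 0.894 with an estimated correlation). The median was 0.76 within letter H and 0.16 within letter Q. The cytosolic chaperone HSP90AA1 measured 1207 ± 130 and 2207 ± 535 CPM (0.87, SE 0.27), and the co-chaperone HSPH1 76.2 ± 37.1 and 122 ± 10.2 CPM (0.67, SE 0.37). HSPA1A and HSPA1B, near-identical HSP70 genes whose reads cannot be told apart with confidence, differed by 0.90 (SE 0.52) and 0.89 (SE 0.51), from 1.97 or more within letter H to −0.20 and −0.19 within letter Q.

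Acute phase proteins rose as a group, with 10 of 12 measured members higher and a median of 0.55 (adjusted p = 2.05e-05, and 0.894 with an estimated correlation). The lipopolysaccharide-binding protein gene LBP differed by 2.07 (SE 0.79), the heme-binding protein gene HPX by 1.20 (SE 0.26), and the orosomucoid genes ORM1 and ORM2, which share reads, by 1.36 (SE 0.51) and 1.33 (SE 0.56). Hepatocyte secreted proteins rose with 16 of 20 higher and a median of 0.31 (adjusted p = 0.00145, and 0.894 with an estimated correlation). Their largest differences were in the apolipoproteins APOA2 (1.82, SE 0.56) and APOH (1.32, SE 0.61), in the fetuin gene AHSG (1.19, SE 0.94) and in plasminogen, PLG (1.07, SE 0.59). Both lists stood lower in the mock library of letter Q than in that of letter H, by a median of −0.96 for acute phase and −1.34 for secreted proteins, and their medians were 0.47 and 0.14 within letter H against 1.31 and 1 within letter Q. Without mock library Q the secreted protein list turned downward (adjusted p = 0.442), and without H2O2 library H it lost its call (0.154).

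Albumin, ALB, lay at 3205 and 1392 CPM in mock libraries H and Q and at 4832 and 2787 CPM in H2O2 libraries H and Q (0.73, SE 0.50, adjusted p = 0.779). AFP lay at 1558 and 385 CPM in mock and at 1752 and 840.3 CPM in H2O2 (0.42, SE 0.72), and GPC3 at 1312 and 533 against 1443 and 866 CPM (0.32, SE 0.50). Without mock library Q the fold changes of AFP and GPC3 were −0.27 and −0.19. The liver transcription factor HNF4A lay at 1247 and 688 CPM in mock and at 636 and 612 CPM in H2O2 (−0.63, SE 0.33). The hepatocyte transcription factor list did not pass (median −0.23, adjusted p = 0.328), and in it the corepressor NR0B2 differed by −1.51 (SE 0.58).

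Immediate early genes rose as a group, with 16 of 17 higher and a median of 0.24 (adjusted p = 0.000514, and 0.894 with an estimated correlation). The transcription factors FOS (1.28, SE 0.58), FOSB (0.95, SE 0.76), EGR1 (0.91, SE 0.70) and EGR2 (0.90, SE 0.33) differed most. The median was 0.84 within letter H and 0.07 within letter Q, and the call was lost without mock library H (adjusted p = 0.216). Without H2O2 library H the value of EGR1 was −0.3. DNA repair genes rose with 13 of 17 higher and a median of 0.32 (adjusted p = 0.0253, and 0.894 with an estimated correlation). The DNA glycosylase NTHL1 (0.54, SE 0.35), BRCA1 (0.50, SE 0.20) and XRCC2 (0.47, SE 0.36) of homologous recombination, and the checkpoint kinase CHEK1 (0.47, SE 0.20) had its largest upward differences. The largest difference of all ran the other way, in the DNA glycosylase NEIL1 (−1.11, SE 0.26, adjusted p = 0.124 over the list alone), which was named after its value was seen. The call of the DNA repair list was lost without mock library H (adjusted p = 0.0531), mock library Q (0.0603) or H2O2 library H (0.371). Wnt target genes rose with 9 of 12 higher and a median of 0.38 (adjusted p = 0.0253, and 0.894 with an estimated correlation). The feedback inhibitors NOTUM (1.10, SE 0.41), NKD1 (0.90, SE 0.37) and AXIN2 (0.82, SE 0.27) and the transcription factor TBX3 (0.49, SE 0.23) led it, and the call was lost without mock library H (adjusted p = 0.225) or H2O2 library H (0.0618).

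Channels that pass H2O2 and NADPH oxidases, which make superoxide or H2O2, fell as a group, with 10 of 11 measured members lower and a median of −0.48 (adjusted p = 0.0042, and 0.894 with an estimated correlation). The oxidases DUOX2 (−1.32, SE 0.39) and NOX1 (−0.97, SE 0.34) and the aquaporins AQP11 (−0.87, SE 0.39) and AQP1 (−0.82, SE 0.52) had the largest downward differences, while AQP9, named after its value was seen, was higher by 1.36 (SE 0.76). NOX1 measured 22.6 ± 1.12 and 11.5 ± 4.89 CPM. The call was lost without mock library Q (adjusted p = 0.0929) or H2O2 library H (0.384). Endoplasmic reticulum stress genes fell with 15 of 17 lower and a median of −0.28 (adjusted p = 0.0311, and 0.894 with an estimated correlation). They included HERPUD1 of protein degradation (−0.56, SE 0.18) and the chaperones DNAJB9 (−0.53, SE 0.30), DNAJC3 (−0.50, SE 0.25) and HSPA5 (−0.42, SE 0.20). That call was lost without mock library H (adjusted p = 0.0943) or H2O2 library Q (0.22), and under 11 of 20 alternative settings in all. Senescence-associated genes fell with 13 of 15 measured members lower and a median of −0.43 (adjusted p = 0.0383, and 0.894 with an estimated correlation). MMP1 (−1.63, SE 0.85), the laminin gene LAMB3 (−1.57, SE 0.74), the cell cycle inhibitor CDKN2B (−0.86, SE 0.83) and TIMP2 (−0.84, SE 0.23) differed most. This list stood higher in library Q than in library H of mock by a median of 0.82. Under 20 alternative settings it lost its call in 8 and reversed in 1. Without mock library Q its test turned upward (adjusted p = 0.95) and CDKN2B had a value of 0.38, and without H2O2 library H the call was lost (adjusted p = 0.74).

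**Figure D2:**
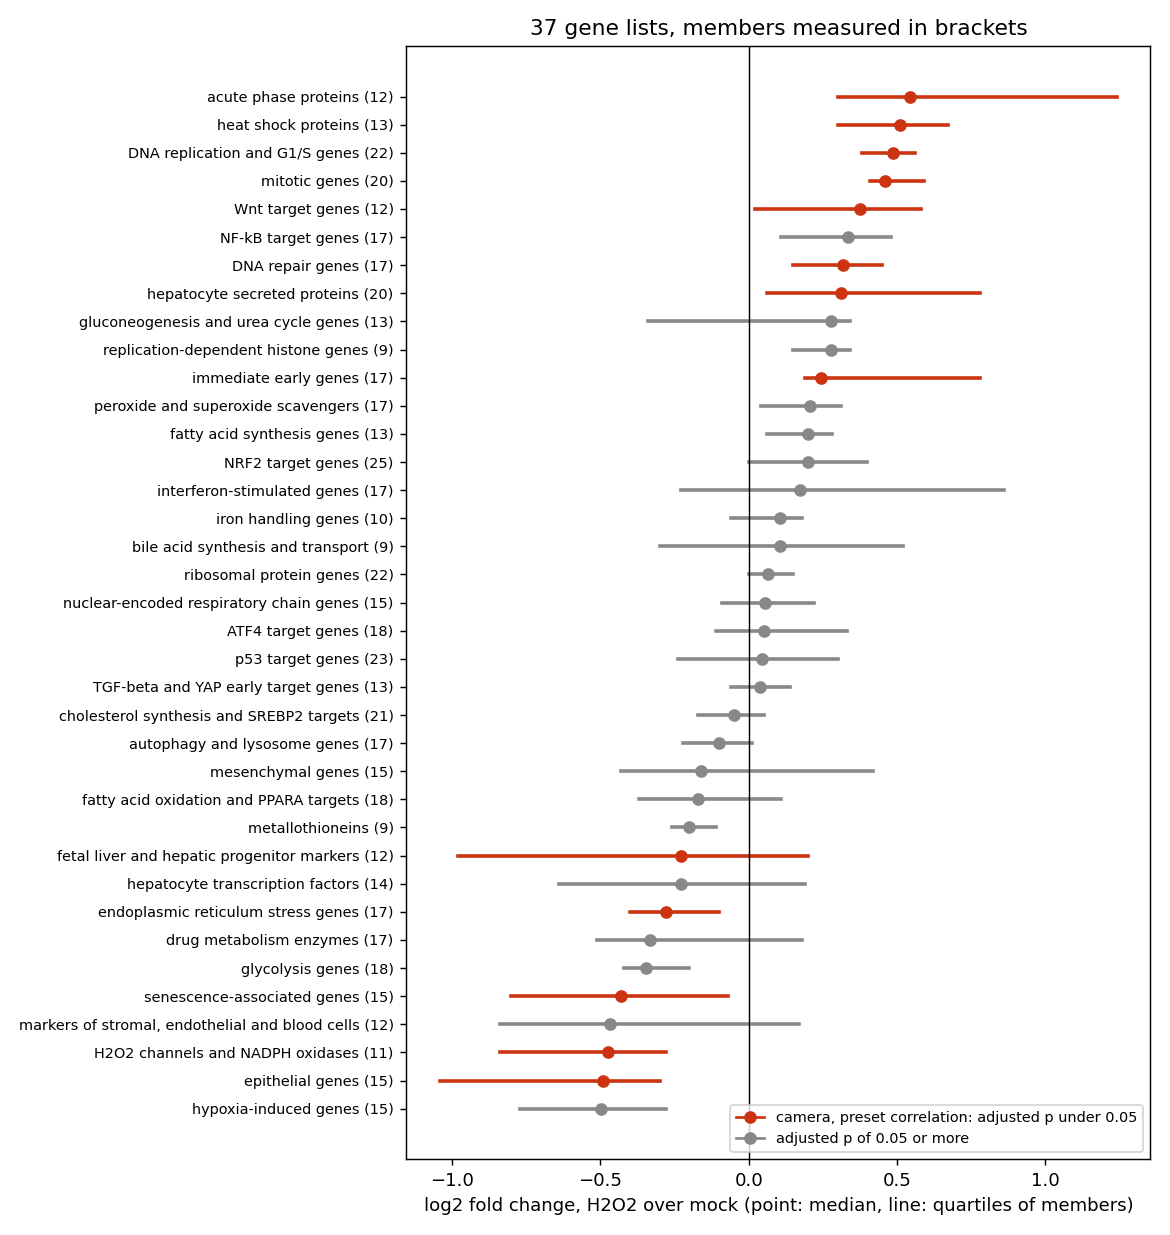
Median (point) and quartiles (line) of the log2 fold change of H2O2 over mock for the members of each of 37 gene lists, with lists past 5% by camera with a preset correlation in red and the others in grey. Of the 13 lists in red, 8 lie to the right of 0 and 5 to the left, and 0 of them passed with an estimated correlation.

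The list of peroxide and superoxide scavengers and that of NRF2 target genes, of the antioxidant response, did not pass as groups. Peroxide and superoxide scavengers had 14 of 17 members higher and a median of 0.21 (adjusted p = 0.0909), with the glutaredoxin GLRX at 0.50 (SE 0.27) and the extracellular glutathione peroxidase GPX3 at 0.42 (SE 0.20). Catalase, CAT, lay at 77.0 and 51.7 CPM in mock libraries H and Q and at 87.6 and 53.8 CPM in H2O2 libraries H and Q (0.14, SE 0.33), and GPX1 at 118 and 91.2 against 134 and 113 CPM (0.24, SE 0.22). NRF2 target genes had a median of 0.20 (adjusted p = 0.263). In that list the aldo-keto reductase AKR1C1, which shares reads with other AKR1C genes, differed by 0.98 (SE 0.45). The heme oxygenase HMOX1 lay at 42.8 and 46.2 CPM in mock and at 17.7 and 32.4 CPM in H2O2 (−0.83, SE 0.33, adjusted p = 0.729). The quinone reductase NQO1 lay at 1931 and 1268 CPM in mock and at 2110.4 and 1229.8 CPM in H2O2 (0.06, SE 0.37). Without H2O2 library H the values of CAT and NQO1 were −0.26 and −0.38, and without mock library Q −0.13 and −0.21.

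Genes of the p53, ATF4 and iron responses did not pass either. The p53 target list had a median of 0.04 (adjusted p = 0.654), with PLK3 at 0.98 (SE 0.41) and AEN at 0.96 (SE 0.32). The cell cycle inhibitor CDKN1A lay at 104 and 116 CPM in mock and at 83.2 and 75.5 CPM in H2O2 (−0.47, SE 0.19), and the stress cytokine gene GDF15 at 33.5 and 44.8 against 27.1 and 34.1 CPM (−0.35, SE 0.24). ATF4 targets had a median of 0.05 (adjusted p = 0.38). Among these ATF3 measured 92.1 ± 60.3 and 271 ± 4.68 CPM (1.56, SE 0.49) and the receptor VLDLR differed by −0.91 (SE 0.34). DDIT3 lay at 188 and 156 CPM in mock and at 198 and 155 CPM in H2O2 (0.04, SE 0.23), with values of −0.15 without H2O2 library H and −0.09 without mock library Q. Iron handling genes had a median of 0.11 (adjusted p = 0.38), with TFR2 at 1.34 (SE 0.74) and ACO1 at 0.49 (SE 0.24). Autophagy and lysosome genes had a median of −0.10 (adjusted p = 0.77), with the transcription factor TFEB at 0.81 (SE 0.34) and the protease CTSD at −0.62 (SE 0.24). Metallothioneins, which share reads with each other, had a median of −0.20 (adjusted p = 0.38), and the low MT1H (−1.51, SE 1.53) and MT1B (−0.66, SE 1.11) turned to 1.65 and 0.43 without mock library Q.

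Hypoxia and glycolysis genes lay apart in opposite directions in the mock libraries, high in H and low in Q. Relative to the mean of the 4 libraries the median hypoxia gene lay at 0.99 in mock library H, −0.65 in mock library Q, 0.02 in H2O2 library H and −0.1 in H2O2 library Q. For glycolysis these values were 0.8, −0.76, 0.11 and −0.15. The differences between groups did not pass, with medians of −0.50 for hypoxia and −0.35 for glycolysis (adjusted p = 0.38 for both). Within letter H the medians were −0.95 and −0.67, and within letter Q they were 0.53 and 0.49. NDRG1 measured 1807 and 364 CPM in mock libraries H and Q and 435 and 477 CPM in the H2O2 libraries (−1.25, SE 0.73). The carbonic anhydrase CA9 differed by −1.22 (SE 0.80), the enolase ENO2 by −1.47 (SE 0.61) and the hexokinase HK1 by −1.08 (SE 0.73). Without mock library H the values of NDRG1 and HK1 were 0.33 and 0.54.

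None of the other metabolic lists passed. Fatty acid synthesis genes had a median of 0.20 (adjusted p = 0.38), with FASN at 0.43 (SE 0.45), which turned to −0.36 without H2O2 library H, and ACSL3 at 0.39 (SE 0.32). Fatty acid oxidation genes had a median of −0.17 (adjusted p = 0.527), with the kinase PDK4 at −0.89 (SE 0.53). Cholesterol synthesis genes had a median of −0.05 (adjusted p = 0.654), with MVK at −0.42 (SE 0.37) and FDFT1 at 0.28 (SE 0.32), and these were 0.01 without mock library H and −0.17 without H2O2 library H. Bile acid genes had a median of 0.10 (adjusted p = 0.475), with the conjugating enzyme BAAT at −0.70 (SE 1.09), which turned to 0.58 without mock library Q and to 0.14 without H2O2 library H, and FGF19 at 0.57 (SE 0.20). Drug metabolism enzymes had a median of −0.33 (adjusted p = 0.475), with CYP1A1 at 0.95 (SE 0.64) and CYP2C8 at −0.73 (SE 0.47). Gluconeogenesis and urea cycle genes had a median of 0.28 but a mean of 0.07 (adjusted p = 0.654), with OTC at 1.01 (SE 0.70) and FBP1 at −0.87 (SE 0.28). Respiratory chain genes had a median of 0.05 (adjusted p = 0.511), with COX4I1 at −0.43 (SE 0.30) and CYC1 at 0.34 (SE 0.36), which turned to −0.07 without H2O2 library H.

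Mesenchymal genes did not pass (adjusted p = 0.958), with a median of −0.16 while the test itself leaned upward. The transcription factor SNAI1, a repressor of CDH1, measured 4.49 ± 0.168 and 9.34 ± 4.69 CPM (1.06, SE 0.39), and the matrix gene SPARC differed by −1.26 (SE 1.09). ZEB1, another repressor of CDH1, measured 73.8 ± 23.1 and 147 ± 15.2 CPM (0.99, SE 0.28, adjusted p = 0.729) and was picked from this list after its values were seen. Of the 15 measured members of the list 10 were lower and 5 higher. Whether either repressor bears on the CDH1 difference was not tested. TGF-beta and YAP early targets had a median of 0.04 (adjusted p = 0.461), with the inhibitory SMAD7 at −0.67 (SE 0.23). NF-kB target genes had 15 of 17 members higher and a median of 0.34 (adjusted p = 0.184), and stood higher in library Q than in library H by 1.25 in mock and 1.01 in H2O2. In that list CCL2 differed by 1.54 (SE 1.14) and TNFAIP3 by 0.76 (SE 0.52), and these were −0.6 and −0.07 without H2O2 library Q. Interferon-stimulated genes had a median of 0.17 (adjusted p = 0.461), with IFI44 at 3.09 (SE 1.31) and IRF7 at −1.62 (SE 0.56). IFI44 lay at 0.0940 and 0.355 CPM in mock libraries H and Q and at 0.269 and 3.60 CPM in H2O2 libraries H and Q.

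The lists fixed as checks did not pass between the treatment groups. Ribosomal protein genes had a median of 0.06 (adjusted p = 0.38), with RPL27 at 0.39 (SE 0.43) and RPS2 at 0.33 (SE 0.48), and these were −0.02 and −0.16 without mock library Q and −0.06 and −0.05 without H2O2 library H. From library H to library Q the median ribosomal protein gene differed by −1.01 in mock and −0.66 in H2O2. This reference set was therefore not level between the letters after scaling, and the cause was not tested. Replication-dependent histone genes, whose reads may be shared between copies, had a median of 0.28 (adjusted p = 0.328), with HIST1H2BJ at 0.71 (SE 0.53) and HIST2H2BE at −0.68 (SE 0.63), the latter 0.12 without mock library Q. Markers of stromal, endothelial and blood cells had a median of −0.47 (adjusted p = 0.38), with COL3A1 at 0.247 ± 0.146 and 0.110 ± 0.105 CPM and DCN at 0.335 ± 0.301 and 0.166 ± 0.000272 CPM. DCN differed by −1.02 (SE 0.76), which turned to 0.44 without mock library Q.

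Of 24235 genes, 47 were separated upward, meaning that the lower H2O2 value of FPKM plus 1 was at least 2 times the higher mock value, and 124 were separated downward. The upward genes were 34 with an mRNA and 13 intergenic RNA models, and the downward genes 84 and 38, with 2 of other kinds. Grouping the libraries by letter gave 426 and 57 genes with Q higher and lower than H, and the crossed grouping gave 22 and 20. On TMM-normalised CPM plus 1, a measure added after the data were seen, the treatment counts were 1 and 42. The count covers large folds at low levels. Upward, FCER2, an immunoglobulin E receptor, had 0 reads in mock and 20 in H2O2, at least 6.44-fold higher, and the model linc_TCONS_l2_00021594 had 0 and 24 reads, at least 7.73-fold higher. The transketolase-like gene TKTL1 (chromosome X) measured 0.0608 ± 0.0156 and 0.752 ± 0.0861 CPM, a 12.2-fold difference in summed counts. Its highest-count model held 9 and 107 reads. The next were linc_TCONS_l2_00008202 (9.82-fold), linc_TCONS_00005546 (9.69-fold), CFHR2 (8.57-fold), MAATS1 (7.32-fold), CD38 (5.51-fold) and linc_TCONS_00005547 (5.41-fold). Of these, linc_TCONS_00005546 lay at 0.119 and 0.373 CPM in H2O2 libraries H and Q, and linc_TCONS_00005547 at 0.114 and 0.422 CPM. Both lay at 0.054 CPM or less in the mock libraries, so their folds lean on H2O2 library Q. FCGR3A had 3 and 21 reads, a ratio of 6.76 (95% counting interval 2.02 to 35.4).

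Downward, the model linc_TCONS_l2_00028819 had 225 reads in mock and 0 in H2O2, at least 77.6-fold lower, with 0.965 CPM in mock library Q and 0.055 CPM in mock library H. REG3A, a secreted lectin, had 27 and 0 reads (at least 9.31-fold lower), AGR3 48 and 0 (at least 16.6-fold), linc_TCONS_l2_00015893 17 and 0 (at least 5.86-fold) and linc_TCONS_00020720 15 and 0 (at least 5.17-fold). OVCH2 had 37 and 1 reads, a ratio of 38.3 (95% counting interval 6.46 to 1550). The adhesion gene CEACAM6 measured 2.29 ± 2.04 and 0.0649 ± 0.0479 CPM (34.5-fold lower), and may share reads with related CEACAM genes. SPDEF, an epithelial transcription factor on chromosome 6, measured 14.3 ± 15.9 and 0.529 ± 0.387 CPM (27.1-fold lower), and PACSIN1 25.7 ± 29.1 and 0.967 ± 0.669 CPM (26.6-fold lower). Their folds lean on mock library H, with 25.5 and 46.3 CPM against 3.10 and 5.08 CPM in mock library Q. These 2 genes neighbour each other, 2578 bases apart on opposite strands in the RefSeq table, and PACSIN1 stood at 1.81, 1.64, 1.79 and 1.93 times SPDEF in the 4 libraries. How the counting used strand was not given in the sources used here. The model linc_TCONS_00011203 on chromosome 6 measured 1.81 ± 0.391 and 0.0673 CPM (26.6-fold lower). In all, 4 intergenic models, this one included, held identical read counts in every library. Read numbers, bounds and intervals are those of each gene's highest-count model, and they cover counting error only. CPM values and the other folds come from counts summed over isoforms, in which a read in several isoforms counts again.

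Gene by gene, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p of 0.05. The lowest adjusted p was 0.174, and 1612 genes had an unadjusted p under 0.05 (689 higher and 923 lower), where 5% of the genes would be 1212. Grouping the libraries by letter gave 3611 such genes and the crossed grouping 113. Differences between the letters enter the spread of this fit, so 1212 is not a sure baseline for chance. Genes picked after their values were seen, as those with the lowest p, included the adhesion phosphatase PTPRM on chromosome 18, with 7.25 ± 0.0855 CPM in mock and 0.678 ± 0.00646 CPM in H2O2 (−3.42, SE 0.24, adjusted p = 0.174). They also included TMC4 (−3.68, SE 0.28), the serine protease PRSS22 (−4.11, SE 0.41), C19orf33 (−4.12, SE 0.43) and CEACAM7 (−3.70, SE 0.39). DESeq2 called 51 genes higher and 125 lower, among them ESRP1, CDH1, EPCAM and PTPRM. Over 5 simulated datasets with 24235 genes in each fit, DESeq2 also called 313 of 120175 unchanged genes (0.26%), against 63 (0.0524%) by edgeR. Of the genes changed 2-, 4- and 8-fold DESeq2 called 64, 244 and 290, and edgeR 12, 157 and 270. Unchanged genes thus made up more than the intended 5% of the simulated calls of both, and a larger share for DESeq2. These counts are pooled over the 5 datasets, so they cannot be set directly against the calls in the real data. With 2 libraries per group and nothing to say that they came from separate cultures, the p-values measure only the spread between these samples. From library H to library Q the median hepatocyte secreted gene differed by −1.34 in mock and −0.68 in H2O2. For hypoxia genes these values were −1.7 and −0.16. Shifts of this size in mock argue against mere repeats of 1 RNA sample there. Whether part of the spread was technical was not tested.

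The 2 libraries of a group differed more from each other than the groups did along the main axis. The first principal component held 50.6% of the variance and placed library Q above library H in both groups (mock −27.7 for H and 66.9 for Q, H2O2 −66.0 for H and 26.8 for Q). The second held 35.2% and placed both H2O2 libraries (36.6 and 36.5) above both mock libraries (−66.9 and −6.3). Both H2O2 values lay above both mock values in 4447 genes and below in 5103, together 39.4% of genes. The share would be 33.3% if the 3 ways of dividing the libraries into pairs were alike. They were not, since the letters set many genes apart, so 33.3% is not a sure baseline for chance. Across genes, which are not independent replicates, the log2 ratios within letter H and within letter Q correlated at r = 0.434.

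**Figure D3:**
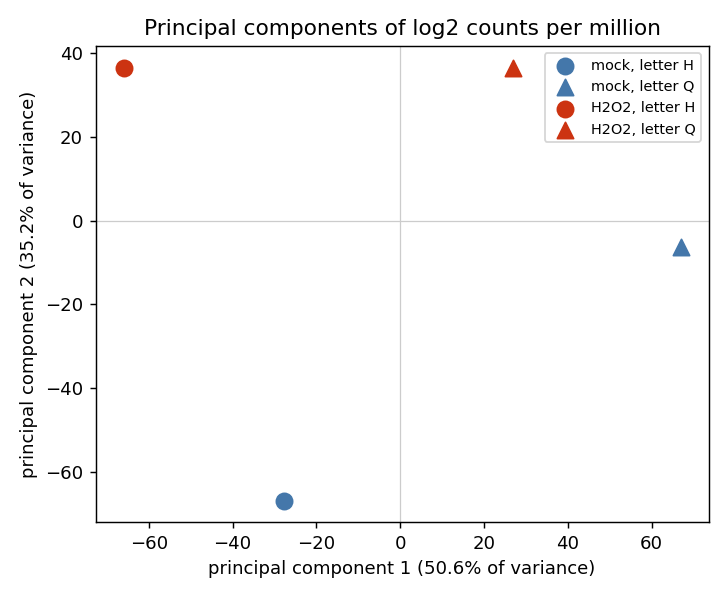
The 4 libraries on the first and second principal components of log2 CPM (50.6% and 35.2% of the variance), with mock in blue, H2O2 in red, circles for letter H and triangles for letter Q. The first axis separates the letters in both groups, and the second places both H2O2 libraries above both mock libraries.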

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

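The tests with the highest-count model of each gene, genes with an mRNA alone and separation on CPM were chosen only after the result was seen. Limma at a pseudocount of 1 was named in advance as the test for FPKM values and became an alternative once the tables were found to hold counts, and all other settings here were planned. The count of 0 genes higher and 0 lower held under every edgeR and limma setting without a block, each library left out included, except that without an expression filter 9 genes were lower. DESeq2 called 51 higher and 125 lower. With the letter as a replicate block edgeR called 21 higher and 60 lower, and deviations from the group means correlated at r = 0.478 between libraries of the same letter, with 1 residual degree of freedom left. The letters are not known to pair the libraries, so this stands as a hint. With the replicate block 15 lists passed, the 13 and also the scavengers (adjusted p = 0.0276) and NF-kB targets (0.00388). DESeq2 and the replicate block shared 52 calls, 52 of them in the same direction. Both fits compare the same counts of the same 4 libraries, so the shared direction is no separate support. Both sets of lower calls count 4 intergenic models with identical reads as 4 genes.

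The 13 gene lists past 5% came to 10 to 18 under the settings with a preset correlation, to 0 with an estimated correlation and to 0 with fry, and the cause was not tested. Without single libraries the adjusted p of the hepatocyte secreted list ranged from 4.2e-20 to 0.44 and that of the senescence list from 5.1e-05 to 0.95, both with a turned direction at the upper end, without mock library Q. Over the 13 lists and their alternatives, 195 outcomes stayed the same, 63 lost the call and 2 reversed.

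The 47 genes separated upward and 124 downward came to 127 and 242 with a pseudocount of 0.1, to 84 and 179 with 0.5, to 28 and 87 at a mean FPKM of at least 5, and to 378 and 443 at 1.5-fold, as a smaller pseudocount or fold asks less and a higher filter tests fewer genes. On CPM plus 1 they came to 1 and 42, where few low genes can reach a 2-fold difference after 1 is added. Leaving out a library asks less as well, and gave 288 (without H2O2 library H) to 616 (without mock library Q) upward and 256 (without H2O2 library H) to 739 (without H2O2 library Q) downward.

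Single genes were followed through the settings only where named. With a library left out, where the lone library is assumed to vary like the other group, 23 of these named genes turned sign and their log2 fold changes had these ranges. Turned without mock library H were NDRG1 (−1.99 to 0.33), HK1 (−1.82 to 0.54) and MVK (−0.83 to 0.01). Turned without mock library Q were MT1H (−4.38 to 1.65), CDKN2B (−2.08 to 0.38), HIST2H2BE (−1.55 to 0.12) and DCN (−1.72 to 0.44). Turned without H2O2 library H were FDFT1 (−0.17 to 0.63), FASN (−0.36 to 0.94), EGR1 (−0.3 to 1.61), CYC1 (−0.07 to 0.75) and AP1M2 (−0.06 to 0.24). Turned without mock library Q and again without H2O2 library H were MT1B (−3.07 to 0.43), BAAT (−2.96 to 0.58), RPL27 (−0.06 to 0.94), RPS2 (−0.16 to 1.07), NQO1 (−0.38 to 0.41), CAT (−0.26 to 0.45), DDIT3 (−0.15 to 0.21), AFP (−0.27 to 1.75) and GPC3 (−0.19 to 1.11). Turned without H2O2 library Q were CCL2 (−0.6 to 2.99) and TNFAIP3 (−0.07 to 1.28). On the FPKM scale DCN turned to 0.25 and 0.09 with limma at pseudocounts of 0.1 and 0.5, and with quantile normalisation DCN turned to 0.05, NQO1 to −0.02 and AP1M2 to −0.01. The cause was not tested. Over the named genes alone, 37 outcomes reversed, 2551 stayed the same and 48 passed the threshold under an alternative alone. At this number of libraries the test recovered 3.58% of simulated 2-fold changes, so a difference of that size below the threshold was not detectable, not absent.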

Other observations

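The tests of scaling, of keratin-rich cells, of dilution by other cells and of the H2O2 library of letter H alone were chosen only after the result was seen, and the list of further epithelial genes was drawn up after the first epithelial list had given its result, before the values of its own genes were looked at.

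Further epithelial genes were lower in the H2O2 libraries too. Of 32 such genes outside the first list 27 were measured, and 25 of them were lower and 2 higher, with a median log2 fold change of −0.59 (unadjusted camera p = 4.46e-12, and 0.0162 with an estimated correlation). The first epithelial list had an unadjusted p of 0.024 with an estimated correlation, which became 0.889 when adjusted over 37 lists, while the second list was tested alone. The proline-rich gene PRR15L differed by −3.47 (SE 1.26), the ion transport regulator FXYD3 by −3.33 (SE 1.26), the glycosyltransferase GALNT3 by −1.74 (SE 0.34), the junction protein gene JUP, plakoglobin, by −1.50 (SE 0.27) and CDS1 by −1.47 (SE 0.26). The 2 higher genes included AP1M2 at 0.09 (SE 0.21), which turned to −0.06 without H2O2 library H. No gene of this list passed over all genes (edgeR, adjusted p = 0.729 for JUP). These genes were named after their values were seen.

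The letters marked large differences that both groups shared. The matrix proteoglycan VCAN lay at 15.2 and 135.1 CPM in mock libraries H and Q and at 19.6 and 100.9 CPM in H2O2 libraries H and Q. The adhesion molecule L1CAM lay at 7.0, 43.7, 3.7 and 26.0 CPM in the same order. Haptoglobin, HP, was lower in the Q libraries, at 76.8, 3.6, 97.6 and 26.5 CPM, as was the organic anion transporter SLC22A7, at 6.3, 0.3, 20.3 and 2.3 CPM. Under the grouping by letter 3611 genes had an unadjusted p under 0.05, against 1612 by treatment and 113 in the crossed grouping, although edgeR called 1 gene by letter. These genes were also named after their values were seen.

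The lower epithelial genes were weighed against 3 technical explanations, and after removing the trend of fold change over GC content and transcript length, known for 96.8% of tested mRNA genes, the list median was −0.57 (95% bootstrap interval −1.15 to −0.22) against −0.49 before, which argues against that trend as the whole cause. The loss of admixed keratin-rich epithelial cells was set against 8 marker genes. KRT7 was the most abundant of them in mock at 0.637 CPM and KRT20 lay at 0.534 CPM, while EPCAM lost 85.5 CPM. This argues against the loss of cells rich in these 8 markers. KRT15, a keratin outside the 8 and picked after its value was seen, was lower in H2O2 (DESeq2, −3.47, adjusted p = 0.00132). Its level was not compared, so the loss of cells rich in other keratins stays open. The scaling test as first written took median log ratio and quantile scaling together, gave a median relative to all genes of −0.47 and counted against scaling, but a single factor per library moves all genes alike, so it was redone on quantile normalisation alone after that result was seen. There the median was −0.55 and the list stayed past its threshold (adjusted p = 6.86e-05 with a preset correlation), but the 95% bootstrap interval (−0.94 to −0.07) reached above the −0.1 set as the limit, so scaling that depends on expression level stays open, with weak evidence against it. A wider epithelial program that is lower in H2O2 also stays open as a hypothesis, with the median of −0.59 in the second list that it would need, and differences in culture density were not tested.

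The differences between the letters were set against 2 explanations. Of 500 genes at least 2-fold apart between the letters in both groups, 84.8% stayed so after the trend over GC content and length was removed, which argues against that trend as the whole cause. For dilution of the hepatoma cells by other cells in Q, the test as first written counted hepatocyte secreted genes more than 1 log2 unit from their list median on the same side in both groups together, and it found 1 of 20, within the 2 that dilution allows. That test was then redone per group, a choice made after its first result was seen: in the mock libraries 5 of 20 genes lay that far out (range −3.76 to 0.56), exactly at the limit set against dilution, and in the H2O2 libraries 1 of 20 did (range −1.58 to 0.48). Dilution therefore stays open, with weak evidence against it in mock, and no biological explanation was tested, since the meaning of the letters was not given in the sources used here.

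The higher cell division genes were set against 2 explanations. After removing the trend over GC content and length the median of the DNA replication and mitotic lists together was 0.42 (95% bootstrap interval 0.38 to 0.50) against 0.47 before, which argues against that trend as the whole cause. Without the H2O2 library of letter H it was 0.30 (0.26 to 0.36), which argues against that library alone for both lists together. These intervals, like those of the epithelial list, resample genes that move together and do not measure the spread between libraries. Relative to the mean of the 4 libraries the median mitotic gene lay at −0.01 in mock library H, −0.49 in mock library Q and 0.06 in H2O2 library Q. Without H2O2 library H the mitotic difference therefore lay mainly against mock library Q. No biological explanation of these genes was tested.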
